A study of Drosophila melanogaster with 6 samples.

How the data were processed

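Total RNA of whole late-stage wandering larvae, about 30 per vial, was labelled directly and hybridised to cDNA arrays, per the labels' protocols. Each of 6 arrays compared 2 RNA samples, one in Cy3 and one in Cy5. The design gives 2 independent biological samples per genotype and a duplicate inter-strain comparison made with the RNA of untreated controls. Untreated larvae spent 90 min at 25 °C.

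The values analysed were the log ratios that the authors deposited, treated here as log2, for 16896 spots on 6 arrays with 0 missing values. Per the labels, the ratio was derived from normalized data. The normalization, the background correction, any filter and the base of the log are not stated. The values have both signs and run from -3.82 to 4.95. A base of 10 at that range would exceed a 16-bit scanner, so base 2 was assumed, but a natural log is not excluded, and fold changes hold only if the base is 2. Array medians lie off 0, so the arrays were not all centred. Direction was set from the values for the heat shock arrays and from the labels' order for the inter-strain arrays, and it stays an inference. Signal intensities and backgrounds were not analysed here, so the signal behind each ratio is unknown.

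Neighbouring spots were taken as the same probe printed 2 times, because all 5818 named spots had the same name as their neighbour. Values of neighbours correlated across spots at r of 0.585 to 0.811 per array, against 0.0974 to 0.233 for neighbours from different probes. Of 8448 probes, 2833 had 1 gene symbol in the platform annotation, 76 had several and 5539 had none. Symbols were updated through the gene table of Release 6 of the genome, which was used for names and chromosome arms only. Spots were averaged into probes and probes with the same symbol into genes. Probes with several symbols or none were tested under their spot number, and control spots could not be told apart from other unnamed spots. Of 2377 named genes, 288 had over 1 probe. For the 216 genes with 2 probes, the group means of both probes correlated across genes at r of 0.489 in dp, 0.280 in hsf4 and 0.171 between strains.

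Differences were tested in limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on all 6 arrays, with a coefficient for each group, no dye term and no replicate block. The hsf4 minus dp contrast tested the difference of the heat responses. The residual degrees of freedom were 3 and the prior added 2.32. P-values are 2-sided and adjusted by the Benjamini-Hochberg method over 7992 units, with a threshold of 0.05. Errors after ± are SDs of 2 arrays, and SE is that of the limma fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. No list that passed with the preset value passed with an estimated correlation, under which camera uses the 3 residual degrees of freedom.

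Before the data were examined, the design, the named genes and 21 gene lists were fixed. Of the lists, 13 had 3 or more measured genes and were tested, 4 had 1 or 2 and 4 had none. The named genes are, for each comparison, up to 10 each way past the threshold with the same sign on every array of the groups compared. Remaining places up to 5 each way went to the smallest unadjusted p, given as values that did not pass. All measured heat-inducible genes and up to 4 genes of each other list were added. Ssl and the unnamed probes other than 10803 and 3131 were named after their values were seen, as was CCT8.

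Alternatives fixed in advance were a dye term, the replicate number as a block, both together, median centring, scaling to the same spread, each probe on its own, a fit of the compared arrays only, a robust prior, a minimum change of 1, a threshold of 0.10, rank-based camera, an estimated inter-gene correlation and leaving out each array. Added after seeing the data were adjustment over named genes only, centring with a dye term, named genes only with a dye term, camera against named genes only, a dye term with an estimated correlation, and lists without some members. The procedure was tested on simulated data with 200 of 7992 units changed by 1 or 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.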

Results

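Transcript ratios were measured in whole wandering larvae of Drosophila melanogaster on 2-colour cDNA arrays. The mutant strain cn bw hsf4 (hsf4 here) carries an allele of Hsf, the gene of the transcription factor that activates heat shock genes. It was compared with the control strain dp cn bw cl (dp here), from which it was derived. The 6 arrays formed 3 groups of 2. In the dp group and in the hsf4 group, each array set larvae kept at 36 °C for 60 min and then at 25 °C for 30 min against untreated larvae of the same strain. In the inter-strain group, each array set untreated hsf4 larvae against untreated dp larvae, using untreated RNA of the kind that also served the heat shock arrays. Dyes were swapped between the arrays of the dp group and of the inter-strain group, while both hsf4 heat shock arrays had the heat-shocked RNA in Cy5. Hsf and the marker genes cn, bw, dp and cl were not among the named genes of the array table (0 of 5 measured), so the genotypes could not be checked in the values.

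Each array gave 16896 spot values, with medians of -0.09 and 0.04 in the dp group, -0.09 and -0.17 in the hsf4 group, and 0.02 and -0.09 in the inter-strain group. The spread of values (SD) ran from 0.37 to 0.52 across arrays. Averaging over the 2 spots of a probe and over the probes of a gene left 7992 units, of which 2377 were named genes and 5615 were probes without a single gene name. The number of arrays, 2 per group, limits the precision of each ratio. Values are log ratios taken as base 2, which the labels do not state, and they likely run as heat shock over untreated and as hsf4 over dp. The basis for the dp and hsf4 groups is that heat shock genes such as Hsp68 had the same sign, above 0, on both dye-swapped dp arrays. That these genes lie above 0 in dp was thus part of the choice of direction and is no separate finding. For the inter-strain arrays, no measured gene fixes the sign, and the basis is the order of the strains in the labels. The dye order argues against the reverse direction, if the dye labels hold. Inter-strain replicate 2 (hsf4 in Cy5) had r of 0.161 to 0.524 with the heat shock arrays of the same order and -0.521 with dp replicate 2. Replicate 1 (hsf4 in Cy3) had r of -0.396 to -0.196 and 0.470 with the same arrays. The reverse direction would set all these signs against the dye order. Every inter-strain sign turns if the ratio runs the other way.

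The dp arrays ask which transcripts a heat shock changes in larvae with the control genotype. In the direction chosen, transcripts of heat shock proteins and chaperones were higher after heat shock. Hsp68, an inducible member of the Hsp70 family, had a log2 ratio of 3.03 ± 0.12 (SD, n = 2), which is 8.19-fold if the base is 2. Its relative Hsc70-2 stood at 2.30 ± 0.03 (SD, n = 2), Droj2, a J-domain co-chaperone, at 1.03 ± 0.15, and Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, at 1.64 ± 0.17. The uncharacterised gene CG16782 stood at 2.10 ± 0.21. Over all 7992 units, limma called 1 higher and 0 lower at an adjusted p under 0.05. The call was the unnamed probe 10803 (log2 ratio 4.26, SE 0.24, adjusted p = 0.0452). The count at an unadjusted p under 0.05 was 273, against 399.6 by chance, and 468 with a term for the dye. Without that term, dye bias on the swapped dp arrays counts as noise, which lowers the count. With a term for the dye in the limma fit, 17 units rose and 0 fell. Of these, 5 were named genes: Hsp68 (adjusted p = 0.0215), Hsc70-2 (0.0449), Gclm (0.0445), CG16782 (0.0455) and Ssl (0.0290, log2 ratio 1.79). Probe 10803 was the 1 unit called by both fits.

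Among the lists of genes fixed in advance, the heat-inducible heat shock genes rose as a set in dp. All 4 measured members, of 19 listed, were above 0, with a median of 0.79. The set held Hsp68, the co-chaperone gene stv (0.88), CG7130 (0.69) and DnaJ-1 (0.41), while none of the Hsp70 genes or small heat shock genes of the list was measured under its name. limma's camera gave an adjusted p = 4.89e-07, and adjusted p = 0.0901 with an estimated correlation. Of the 4, 2 passed when adjusted over the list alone (Hsp68 and stv) and 0 over all genes. DnaJ-1 was the mean of 8 probes that ranged from 0.19 to 0.71. The constitutive chaperones and co-chaperones also rose as a set. Of 15 measured members, 14 were above 0 and the median was 0.40. CCT1, STUB1, Torsin, Hsp60B and Hsp60C had opposite signs on the dp arrays (-0.24 and 1.36 for CCT1), and the others had the same sign. The chaperone list had a camera adjusted p = 1.10e-10, or adjusted p = 0.0901 with an estimated correlation. When adjusted over the list alone, 5 passed, against 0 over all genes: Hsc70-2, Hsc70-1 (1.10), Droj2, and the chaperonin subunits CCT8 (0.76) and CCT2 (0.74). The 3 probes of Hsc70-1 disagreed, from -0.13 to 1.80. Hsp70 transcripts could bind the probes of Hsc70-1 and Hsc70-2, which was not tested for these 2 genes. Without both, a subset chosen after the results were seen, 12 of 13 chaperones were above 0 with a median of 0.37.

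Proteasome subunits shifted down by a small amount in dp, with 13 of 14 measured members below 0 and a median of -0.16. Their camera result was an adjusted p = 0.0324, and adjusted p = 0.349 with an estimated correlation. The adjusted p was 0.139 without dp replicate 1, 0.181 without dp replicate 2 and 0.0732 with the dye term. Examples are Prosbeta7 (-0.31), Rpt5 (-0.22) and Rpn1 (-0.19), and 0 of the 14 passed when adjusted over the list alone or over all genes. The 6 members with testis-type names, such as Rpt4R (-0.27), were not needed for the shift, since the other 8 were all below 0 with a median of -0.18. The other 10 lists did not pass in dp. The antioxidant and detoxification genes had a median of 0.03. Only 3 of 30 listed were measured, Sod2, Prx3 and Trx2, so that median does not cover the rest of the list. Medians were -0.08 for ecdysone-responsive genes, -0.16 for cuticle proteins and -0.05 for muscle proteins. They were 0.02 for neuronal and synaptic genes and 0.02 for hemocyte genes. Testis genes had a median of -0.19, ribosomal proteins 0.03 and respiratory chain genes -0.02. The translation and stress list, with PEK, Atg8a, Sesn, foxo and crc measured, had a median of -0.15.

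No named gene passed as lower in dp. Those of smallest unadjusted p below 0 were CG5171 (-1.14 ± 0.17, SD, n = 2), kuk, a nuclear envelope protein gene (-0.55 ± 0.18), Fim, the actin-bundling fimbrin (-0.42 ± 0.03), the RNA polymerase II subunit Polr2H (-0.43 ± 0.13) and the RNA-binding protein gene Fmr1 (-0.41 ± 0.10). Adjusted p-values in limma for these 5 ran from 0.855 to 0.999. In simulated data with the dye bias estimated here, the fit without a dye term recovered 17 of 100 units changed by 1 and 87 of 100 changed by 2 in the dp group, with 0 false calls. The fit with the term recovered 97 and 100, with 18 false calls among the unchanged units. Simulated for the hsf4 group, the fit with the term recovered 66 of 100 units changed by 1 and 100 of 100 changed by 2, with 16 false calls. The simulated dye bias and spread came from the fit with the term, the noise was independent between arrays, and 200 units changed at once. Fewer changed units make the adjusted threshold stricter, so recovery in the real data can be lower.

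**Figure D1:**
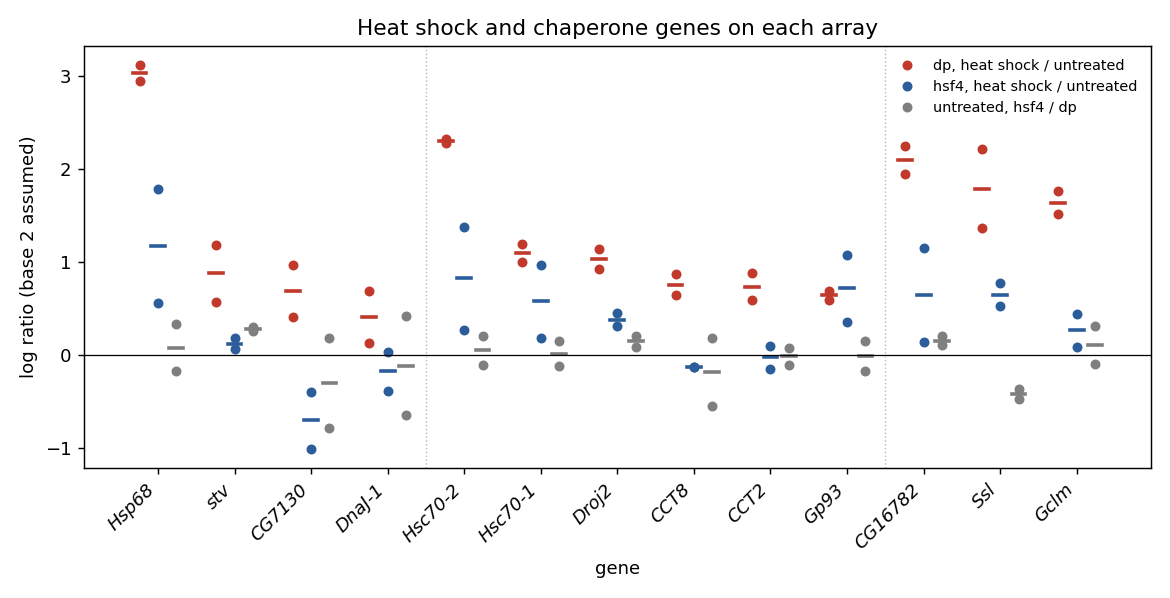
Log ratio (base 2 assumed, vertical axis) of 13 genes on each of the 6 arrays, with points for arrays and short bars for group means (n = 2). From left to right, the blocks hold heat-inducible genes, constitutive chaperones and 3 further genes called in dp with the dye term. The chaperones drawn are those with the highest dp means, not the whole measured list. Hsp68 stood at 2.95 and 3.12 on the dp arrays and at 0.57 and 1.79 on the hsf4 arrays.

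The hsf4 arrays ask what the same heat shock does in larvae with the mutant factor. Hsp68 had a log2 ratio of 1.18 ± 0.86 (SD, n = 2), with 0.57 on one array and 1.79 on the other. Hsc70-2 stood at 0.83 ± 0.79, Hsc70-1 at 0.58 ± 0.56, the endoplasmic reticulum chaperone gene Gp93 at 0.72 ± 0.51 and Droj2 at 0.38 ± 0.10, and none of these passed over all genes. limma called 1 unit higher and 0 lower among 7992. It was the unnamed probe 3131 (log2 ratio 3.43, SE 0.19, adjusted p = 0.0445), which stood at 2.04 in dp and was also called there with the dye term. The count at an unadjusted p under 0.05 was 957, against 399.6 by chance, with 119 units higher and 838 lower. With the dye term the count was 642. Without that term, dye bias enters the means of the unswapped hsf4 arrays, so this count cannot be set against that of dp. The median of all units was -0.16 in this group. With each array centred on its median, the split was 340 higher and 456 lower, and with the dye term it was 102 and 540. It was 165 and 560 without hsf4 replicate 2, and 68 and 911 without either inter-strain array.

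Neither the heat shock genes nor the chaperones passed as sets in hsf4. The heat-inducible list had 2 of 4 members above 0, a median of -0.02 (0.14 above the median of all units) and a camera adjusted p = 0.514. The chaperone list had 5 of 15 members above 0 (8 of 15 after centring), a median of -0.13 (0.03 above the median of all units) and a camera adjusted p = 0.422. With the dye term both medians turned above 0, to 0.10 for the heat-inducible genes and 0.04 for the chaperones. Hsp68 passed when adjusted over the heat-inducible list alone, and no chaperone passed over its own list. CG7130 was at -0.70 ± 0.43 (SD, n = 2), or -0.32 with the dye term, and the 8 probes of DnaJ-1 spread from -0.71 to 0.85 around a mean of -0.17, which turned to 0.23 with the dye term. The translation and stress list, with 4 of 5 genes above 0 and a median of 0.08, had the smallest camera adjusted p of the 13 lists, 0.177. Muscle genes were all below 0 (0 of 8 above, median -0.16, close to the median of all units), and 1 of them passed as lower over the list alone. That gene was Prm, the muscle protein paramyosin (-0.53 ± 0.02), whose limma adjusted p over the list was 0.0433, and 0.247 with the dye term.

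No named gene passed in hsf4, and those of smallest unadjusted p lay between -1.02 and 1.19. Above 0 were CG13868 (1.19 ± 0.14, SD, n = 2), the ceramide kinase gene Cerk (0.85 ± 0.07), BTBD9 (0.69 ± 0.10) and brwl (0.94 ± 0.29). Below 0 were NKAIN (-1.02 ± 0.22), CG9257 (-0.95 ± 0.07), Zmynd8 (-0.86 ± 0.06), CG4332 (-0.90 ± 0.13) and CG30355 (-0.87 ± 0.11). All of these had an adjusted p of 0.317 in limma. Both arrays carried the same dye order, so a dye effect does not cancel in these means.

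The contrast of the heat responses asks which transcripts respond differently in the mutant. Heat-inducible genes and chaperones responded less in hsf4 than in dp as sets. All 4 heat-inducible genes had a lower mean response, by a median of -1.08, or -0.92 relative to the median of all units (-0.15). The differences were -1.86 for Hsp68, -1.39 for CG7130, -0.76 for stv and -0.58 for DnaJ-1. With the dye term they were -1.69, -1.01, -0.93 and -0.18 in the same order. The 8 probes of DnaJ-1 disagreed, from -1.22 to 0.26 with 2 above 0, and may not all measure that gene. These 2 probes lay above 0 on every heat shock array, with means of 0.31 and 0.71 in dp and 0.56 and 0.85 in hsf4. The lower mean of DnaJ-1 thus came from its other probes. camera gave an adjusted p = 0.00847, and adjusted p = 0.467 with an estimated correlation. When adjusted over the list alone 3 of 4 passed, and 0 over all genes. Of the 15 chaperones, 13 had a lower response (15 of 15 with arrays scaled to the same spread), by a median of -0.52, or -0.37 relative to all units. Their camera result was an adjusted p = 0.00419, and adjusted p = 0.467 with an estimated correlation, and 0 passed over the list alone. The heat-inducible result had an adjusted p = 0.0526 without dp replicate 1 and 0.124 without hsf4 replicate 1. The chaperone result had an adjusted p = 0.361 without hsf4 replicate 1.

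No single unit passed for the difference. limma called 0 of 7992, the smallest adjusted p was 0.661, and the count at an unadjusted p under 0.05 was 479, with 77 higher and 402 lower in hsf4 (162 and 289 after centring). That split was 38 and 636 without dp replicate 1, and 51 and 167 without dp replicate 2. The named genes of smallest unadjusted p with a lower response in hsf4 were Gasz, a gene of the piRNA pathway (-1.45, SE 0.24), Gclm (-1.37, SE 0.24), CG9257 (-1.01, SE 0.18), the mitochondrial co-chaperonin gene CG11267 (-1.59, SE 0.30) and Ugt36F1 (-1.57, SE 0.30). Those with a higher response were CG13868 (0.76, SE 0.19), CG18754 (0.77, SE 0.20), the translational repressor gene pum (0.65, SE 0.19), brwl (0.79, SE 0.25) and shep (0.52, SE 0.17). Each of these 10 had an adjusted p of 0.727. Of the 17 units called in dp with the dye term, 16 had a lower estimate in hsf4, and for 15 both hsf4 arrays lay below both dp arrays. Their median log2 ratio was 2.19 in dp and 0.41 in hsf4 in that fit. Because these units were picked for being high in dp, part of that gap is expected from the choice. The other 11 lists did not pass for the difference, with medians from -0.51 for hemocyte genes to 0.23 for the translation and stress list. In the respiratory chain list, 1 gene, ND-B8, passed as lower in hsf4 when adjusted over the list alone. Its log2 ratio was 0.64 in dp and -0.49 in hsf4. The limma adjusted p of its difference over the list was 0.0328, and 0.0593 with the dye term.

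**Figure D2:**
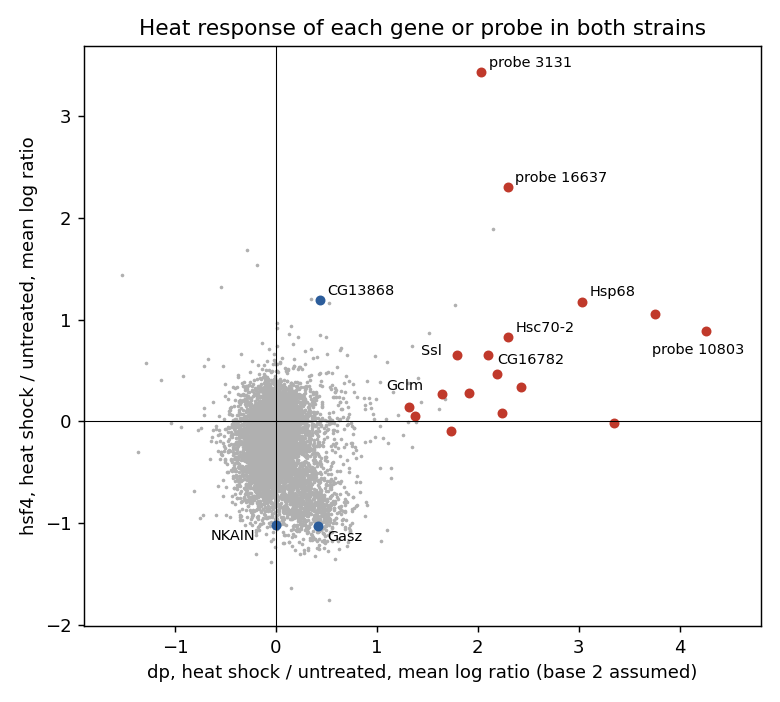
Mean log ratio after heat shock (base 2 assumed, n = 2 arrays per mean) in dp (horizontal axis) and hsf4 (vertical axis) for 7992 genes and unnamed probes. Red points are the 17 units called in dp with the dye term, and blue points are 3 other named genes. Hsp68 lies at 3.03 in dp and 1.18 in hsf4, and probe 3131 lies at 2.04 and 3.43.

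The inter-strain arrays ask how the untreated strains differ before any heat shock. The largest named difference was in mag, which encodes the gut lipase magro. Its log2 ratio was 2.24 ± 0.40 (SD, n = 2), likely in favour of hsf4, with an adjusted p = 0.182 in limma and 0.0226 with the dye term. On the other side of 0, the homeobox gene Drgx stood at -1.72 ± 0.23 and hwt at -1.41 ± 0.03, with adjusted p of 0.260 and 0.509. Also below 0 on both arrays were CG10343 (-0.80 ± 0.05), CG33710 (-0.995 ± 0.32) and CG7778 (-1.07 ± 0.34). Above 0 were BRWD3 (0.72 ± 0.20), CG17568 (0.96 ± 0.29), the bHLH gene Oli (0.97 ± 0.03) and idc (0.63 ± 0.20). limma called 0 of 7992 units, with 622 at an unadjusted p under 0.05 (307 above 0 and 315 below). The split was 117 and 450 without inter-strain replicate 1, 247 and 74 without replicate 2, and 321 and 506 with the dye term. The fit with a dye term called 4, namely mag and the unnamed probes 13339 (-2.51), 5045 (-2.15) and 6629 (-1.94).

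No difference of heat shock or chaperone genes passed as a set between the untreated strains. The heat-inducible list had a median of -0.01 and the chaperone list a median of -0.01, with camera adjusted p of 0.828 and 0.655. Hsp68 was at 0.08 ± 0.35 (SD, n = 2) and Hsc70-2 at 0.05 ± 0.23. None of the 13 lists passed. The ecdysone-responsive genes had 0 of 6 members above 0 and a median of -0.22 (adjusted p = 0.275), with ImpL2 at -0.57 ± 0.06 and ImpE3 at -0.49 ± 0.33. The muscle genes had 6 of 8 above 0 and a median of 0.06 (adjusted p = 0.275), with Tm2, a tropomyosin, at 0.85 ± 0.57. Respiratory chain genes had 5 of 6 below 0 and a median of -0.25 (adjusted p = 0.275).

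The markers that name the strains lie on chromosome 2, which raises the question whether strain differences gather there. Among the top 5% of named genes by inter-strain difference, 29 of 118 lay on arm 2L, or 24.6% against 21.0% of all named genes. The odds ratio was 1.24 (95% interval 0.774 to 1.93, p = 0.354, Fisher's exact test, 2-sided, adjusted over 5 arms 0.589). For arm 2R it was 24 of 118, with an odds ratio of 1.08 (95% interval 0.650 to 1.73, p = 0.720, Fisher's exact test, adjusted 0.720). No arm passed.

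Across the 7992 genes and probes, which are not independent replicates, the mean heat responses of dp and hsf4 had a Pearson r of -0.0855 and a Spearman rho of -0.0765. Over named genes alone r was 0.0208. With the dye term r was 0.211. Single dp and hsf4 arrays gave r from -0.451 to 0.459, depending on the dye order. The inter-strain values shared untreated RNA with the heat responses, which alone gives r of 0.502 with dp and -0.501 with hsf4 if all noise lay in the RNA (100 simulations of unchanged genes). The observed r was 0.0304 with dp (covariance 0.00223 against a simulated 0.0345) and 0.0903 with hsf4 (covariance 0.00901 against -0.0346). With the dye term the value for hsf4 turned to -0.0643 (covariance -0.00548), and over named genes alone it was 0.225 without that term. All 7 pairs of arrays of the same dye order correlated above 0, at r from 0.161 to 0.524, and all 8 pairs of opposite order below 0, at r from -0.521 to -0.126.

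**Figure D3:**
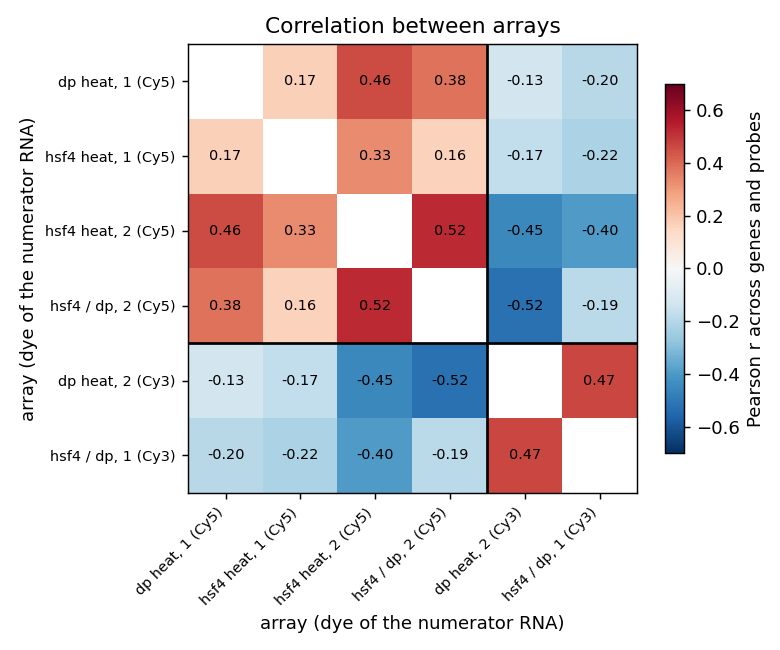
Pearson r across genes and probes for each pair of the 6 arrays, ordered by the dye of the heat-shocked or hsf4 RNA (Cy5 for the first 4, Cy3 for the last 2). Pairs of the same dye order ran from 0.161 to 0.524 and pairs of opposite order from -0.521 to -0.126.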

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

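The list without Hsc70-1 and Hsc70-2 and the explanations weighed were chosen after the results were seen. So were centring with the dye term, the dye term with an estimated correlation, and the dye effect from the 4 other arrays. The fits behind the other values were planned. The gene lists whose heat response differed between the strains by a test of the difference itself were the heat-inducible genes (median difference -1.08) and the constitutive chaperones (median difference -0.52).

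The heat-inducible genes and chaperones responded less in hsf4 than in dp. Dye bias cancels in dp but not in hsf4. With the dye term the medians were -0.97 and -0.51. limma's camera gave an adjusted p of 0.00739 for both, or adjusted p = 0.603 with an estimated correlation. These medians argue against a dye bias shared with the dp and inter-strain arrays as the whole cause. A dye effect particular to the hsf4 arrays cannot be estimated, since both had the same dye order, and stays open. Binding of Hsp70 transcripts to the probes of their cognates is argued against as the whole cause of the chaperone gap, because without Hsc70-1 and Hsc70-2 the median was -0.49, with 11 of 13 genes below 0. The hsf4 genotype remains a possible explanation that the design names and these values do not test apart from other differences between the strains. Without the dye term, the adjusted p with an estimated correlation (-0.0252 and 0.0700) was 0.467 for both lists, and with the preset one but without hsf4 replicate 1 it was 0.124 and 0.361 (0.0526 without dp replicate 1 for the heat-inducible genes).

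In hsf4, 838 of the 957 units at an unadjusted p under 0.05 were lower after heat shock. The dye effect estimated from the 4 other arrays correlated with the hsf4 means across units at r = 0.578. Lower units made up 87.6% before any correction and still 84.1% with the dye term. That argues against a dye bias shared with the dp and inter-strain arrays as the whole cause of the imbalance. The term cannot remove a dye effect particular to the hsf4 arrays, which were not swapped, so that stays open. Array medians lay below 0 where the heat-shocked or hsf4 RNA was in Cy5 and above 0 elsewhere, so dye and medians are not fully separate. Array medians off 0 stay open as well, since lower units made up 57.3% after centring and 65.3% after centring with the dye term, and centring by itself pulls the balance towards even. A broad true decrease would be removed by centring as well and stays open.

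Arrays correlated by dye order and not by comparison, as the values in the report show, and the dye term itself had an adjusted p under 0.05 in limma for 629 of 7992 units. Differences between the RNAs keep their sign in a dye swap, which would put r between the swapped arrays of a group above 0. That r was -0.126 in dp and -0.189 between strains, or -0.018 and 0.075 over named genes alone. These values argue against RNA differences as the main source of the pattern and go with a probe-specific dye bias. The dye effect from the dp and inter-strain arrays correlated with the hsf4 means at r = 0.578. No further test of the pattern was made.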

How the results depend on the processing

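The cause of changes was not tested unless stated. For dp, the count of 1 unit past the threshold became 17 with the dye term, 28 with the replicate block and dye term, 4 with centring, 13 with scaling, 9 at a threshold of 0.10, 25 with centring and dye term, 5 over named genes only with the dye term, and 0 over named genes only or with the dp arrays alone. For hsf4, the count of 1 became 2 with the hsf4 arrays alone, and 0 with scaling, over named genes only, and over named genes only with the dye term. The inter-strain count of 0 became 4 with the dye term, 6 with centring and dye term and 2 over named genes only with the dye term. Leaving out each array in turn gave counts from 0 to 0 in all 4 comparisons, each lone array being assumed to vary like the other groups, and fewer arrays leave fewer degrees of freedom. Settings not named here or in the next paragraph gave the same counts.

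No label ties arrays of the same number to the same RNA or day. Within the dp group or the inter-strain group alone, the number cannot be told from dye. The number goes with opposite dye orders in these groups, so across them a shared number effect gives deviations that correlate above 0. A shared dye effect gives deviations that correlate below 0. Deviations from the group means correlated at -0.392 between dp and hsf4, -0.704 between dp and inter-strain arrays and 0.378 between hsf4 and inter-strain arrays. The value of -0.704 has the sign of a dye effect, though a smaller number effect beside it is not excluded. With the replicate block the count was 0 for dp, 0 for hsf4, 0 between strains and 0 for the difference. With the replicate block and dye term, it was 28 for dp, 1 for hsf4, 17 between strains and 3 for the difference.

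The heat-inducible list in dp had a median of 0.79 in every setting that ended its call, with an adjusted p of 0.0901 with an estimated correlation and 0.247 with the dye term as well. For the chaperones in dp (0.40) the values were the same 0.0901 and 0.247. For the difference, the heat-inducible median of -1.08 had an adjusted p of 0.467 with an estimated correlation, and the median of -0.97 with the dye term as well had 0.603. The chaperone medians of -0.52 and -0.51 had 0.467 and 0.603. Leaving out each array gave medians of the difference from -1.26 to -0.95 for the heat-inducible genes, with adjusted p of 0.0526 without dp replicate 1 and 0.124 without hsf4 replicate 1. For the chaperones they ran from -0.63 to -0.43, with an adjusted p of 0.361 without hsf4 replicate 1. Over all lists, 760 results kept their side of the threshold, 17 no longer passed and 3 newly passed. Of the 760, 66 changed sign, none of them past the threshold in either setting. The 3 newly passed results were testis genes in dp, without hsf4 replicate 1 and without hsf4 replicate 2 (median -0.19 each time), and ecdysone-responsive genes for the difference. The latter had a median of 0.15 without hsf4 replicate 2. For named genes and probes, 2845 kept their side, 14 no longer passed and 12 newly passed, and 111 of the 2845 changed sign, none of them past the threshold.

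The r of the dp and hsf4 heat responses turned from -0.0855 to 0.211 with the dye term, and leaving out each array gave r from -0.399 (without dp replicate 1) to 0.400 (without dp replicate 2). The dye order of the remaining dp array matched hsf4 where r was above 0 and opposed it where r was below.

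The planned treatment of missing values gave no result, since none is missing. Signal over background is unknown, so faint spots could not be set aside.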

Other observations

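The fits and the comparison of chromosome arms in this part were planned, while the probes described and the limit set for the chromosome hypothesis were chosen after the results were seen. Unnamed probes held the largest heat responses. With the dye term, probe 10803 stood at 4.26 in dp and 0.74 in hsf4, probe 11089 at 3.75 and 0.56, and probe 4187 at 3.35 and 0.23. Probe 11589 stood at 2.24 and -0.16, below Hsp68 (3.03) and Hsc70-2 (2.30) in dp. The difference for 10803 and for 11589 had an adjusted p of 0.151 in limma, that for 4187 of 0.286 and that for 11089 of 0.549. The fit with the replicate block and dye term called 10803 and 4187 among its 3 units. Probes 3131 and 16637 were high in both strains, at 2.04 and 3.36 for 3131 and at 2.30 and 1.97 for 16637.

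Some genes outside the tested lists belong to stress or tissue lists with 1 or 2 measured members. The small heat shock protein relatives CG4461 and CG7409 had opposite signs on the dp arrays, -0.69 and 1.01 for CG4461 and -0.38 and 1.15 for CG7409. The stress peptide gene TotF did likewise, at -0.46 and 0.89. The fat body protein gene Fbp2 stood at -0.64 ± 0.02 (SD, n = 2) after heat shock in hsf4 and at -0.04 ± 0.22 in dp, and the lipoprotein gene apolpp at 0.11 ± 0.63 and -0.08 ± 0.23. No measured gene represented the antimicrobial, salivary glue or glycolysis lists.

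The unnamed probes 5045 and 6629 were lower in untreated hsf4 than in untreated dp in the likely direction (-2.15 and -1.94) and higher after heat shock in hsf4 (1.88 and 1.91 with the dye term). In dp, their heat shock arrays gave -0.62 and 0.04 for 5045 and -0.59 and 0.20 for 6629. The untreated hsf4 RNA enters both ratios with opposite sign, so a low value in it alone would give this pair of values.

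A hypothesis that strain differences gather on chromosome 2 was not borne out or excluded. The odds ratio for arm 2L was 1.24 among the top 5% of genes, with an upper 95% limit of 1.93.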
